A study of Mus musculus with 4 samples.

How the data were processed

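The study measured total RNA from SVEC4-10 cells on Affymetrix-type 3' expression arrays. There was 1 array each for untreated cells, cells with the insert-free vector, cells with the Mical2 hairpin and cells with the Mical3 hairpin. Groups were taken from the titles and the condition given in the labels. Per the labels, the RNA on each array was a pool of 3 biological replicates, and biotin-labelled complementary RNA was hybridised. The values the authors deposited are log2 expression levels, 1 per probe set and array, given to 2 decimals. They were computed with RMA, a method that corrects background, applies quantile normalization and summarises the probes of a probe set, per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The 4 columns had nearly the same quantiles, with medians from 5.40 to 5.44.

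The deposited values were used without further scaling. Of the 45101 probe sets, 64 are control probe sets of the manufacturer, 34945 have exactly 1 gene symbol in the platform annotation, 932 have several and 9160 have none. Symbols were updated through Entrez gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which matched 34741 of the probe sets with 1 symbol. For the other 204 the annotation's own symbol was kept. Probe sets with several symbols or none were left out of the comparisons between genes. A gene with more than 1 probe set was represented by the probe set with the highest mean over the 4 arrays, which gave 18193 genes, 12166 of them at or above the floor on some array. The gene table served for names and for which genes neighbour each other, and no coordinates are given. A first test of neighbouring genes compared medians of stretches of 25 genes with the highest of random orders, a limit that a change of 1 copy could not pass, and it was replaced, after its result was seen, by a comparison of the nearest neighbours of called genes.

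With 1 array per group no test can be run, so a gene was called by size alone. It had to differ by at least 1 on the log2 scale (2-fold), with the higher of the compared levels at or above the floor of 5.41, the median of the whole table. A hairpin array had to differ from the vector array and from the untreated array in the same direction. The vector was compared with the untreated array, the hairpin arrays with each other, and each array with the other 3. The number of arrays limits the precision, and no error can be given for a level. The spread between 2 probe sets of a gene gives a lower bound, with a standard deviation of 0.33 for the difference of the Mical2 hairpin array from the vector array, 0.36 for the Mical3 hairpin array and 0.26 for the vector from the untreated array. Probe sets near background have compressed differences after RMA, so small differences of dim genes are understated.

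These rules, the gene lists and the alternatives were fixed before the data were examined. The 37 gene lists covered the MICAL family, endothelial identity, angiogenesis, actin and SRF regulation, matrix, cell cycle, stress, interferon and metabolism, and markers of other cell types. For each list the members called by the size rule were counted, and the median difference was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these arrays and is no p-value. Members of a list can move together for reasons the random lists do not share, and lists overlap. There were 222 such comparisons, and the result of 1 list is not reported here. The genes named in the text are the first 12 higher and the first 12 lower for the Mical2 hairpin and the first 8 and 8 for the Mical3 hairpin, ranked by the smaller of the 2 absolute differences from the controls, and the first 5 and 5 by absolute difference for the vector against the untreated array and for the hairpin arrays against each other. Up to 4 members of each list with the largest absolute difference from the vector array were named, with any member that passed the size rule, and so were the first 4 higher and 4 lower of the genes shared by both hairpin arrays and the MICAL family. Predicted genes without a proper name were skipped. Not every list member that the rule would allow is printed. For overlaps and correlations that share control arrays, 200 unchanged arrays were simulated against the same controls from the spread between the 2 controls.

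The size rule was tested on simulated data for the Mical2 hairpin against both controls, run on 18193 genes. Of 50 genes set higher by 1.5 on the log2 scale 33 were recovered, of 50 set lower by 1.5 it was 35, and at a change of 3 it was 50 of 50 in each direction. Of 17993 unchanged genes 136 were called when every array was given the spread between the 2 controls. For the list percentiles, run on the vector against the untreated array with 200 random lists of 30 genes, 9 unshifted lists lay outside the central 95% and all 200 lists shifted by 0.5 did. Alternatives were the vector array, the untreated array or their mean as the only control, a fold of 1.5 or 3, no floor or a floor at the 75th percentile, the mean of a gene's probe sets or the one with the highest variance, leaving out probe sets open to cross-hybridisation, a repeated quantile normalization, a loess fit along the mean level, 16 added on the linear scale, and random lists not matched on level. The positions of the hairpin targets and the seed sites of the hairpins in other transcripts were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.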

Results

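The series measured messenger RNA in SVEC4-10 cells, an endothelial line made from mouse lymph node vessels by transformation with SV40. There were 4 arrays in 4 groups, with 1 array each. The untreated array held cells that had received no vector, and the vector array held cells transduced with an insert-free lentiviral vector. The other 2 arrays held cells transduced with the same backbone expressing a short hairpin RNA against Mical2 or against Mical3, and transduced cells were selected with blasticidin. Each array was hybridised with RNA pooled from 3 biological replicates, so the spread between replicates cannot be seen, no test was possible and no p-value is given. The number of arrays limits the precision. A gene is called higher or lower below when it passed a rule of size (at least 2-fold, with the higher level at or above the floor of 5.41 on the log2 scale), and values are log2 levels or log2 differences. Over all 45101 probe sets, the array medians lay between 5.40 and 5.44, and the correlation between arrays across probe sets, which are not independent replicates, ran from 0.978 (vector and Mical3 hairpin) to 0.990 (untreated and Mical2 hairpin).

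The targeted genes came first, as a check of the labels. Mical2 encodes a redox enzyme that oxidises and so disassembles actin filaments and is known to promote transcription by SRF with its cofactors of the MRTF family. Mical2 was read by 2 probe sets. On the array labelled Mical2 knock-down they stood at 5.53 and 5.53, against 4.64 and 5.14 on the vector array and 5.33 and 5.60 on the untreated array. Their highest levels were on the array labelled Mical3 knock-down, at 6.0 and 6.08. Mical3, a related enzyme, was at 7.24 on the array labelled Mical3 knock-down, 6.83 on the array labelled Mical2 knock-down, 7.29 on the vector array and 7.39 on the untreated array. Another probe set, annotated to both Mical3 and Gm43915, lay below the floor throughout. It read 4.71, 4.81, 4.83 and 4.90 in the same order. Neither target was therefore lower than on both control arrays by 2-fold on the array of its own hairpin, which goes against the labels as far as transcript levels go. For that reason the 2 hairpin arrays are named below by their labels only, as the array labelled Mical2 and the array labelled Mical3, and every direction drawn from them is a difference between labelled arrays. The hairpin stems have 23 bases, with the sense strands AACATGGCAGGAGCAGGAAGCAC for Mical2 and AAGTGGAGGAGATTAGTGGCGTG for Mical3, and their positions in the transcripts were not analysed here.

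Among the relatives, Mical1 read 8.0 on the array labelled Mical2 and on the vector array, 7.59 on the untreated array and 6.82 on the array labelled Mical3. Its second probe set read 7.51, 7.43, 6.90 and 6.37 in the same order. Micall1 lay between 8.47 and 8.97 on all 4 arrays. Micall2 was at 7.36 on the array labelled Mical2 and 7.19 on the untreated array, but at 6.01 on the vector array and 5.56 on the array labelled Mical3. Micalcl, the gene next to Mical2 in the gene order, which is outside the list fixed for this family and was named after its values were seen, was called higher on the array labelled Mical2 (6.06, against 4.76 on the vector array and 4.96 on the untreated array).

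**Figure D1:**
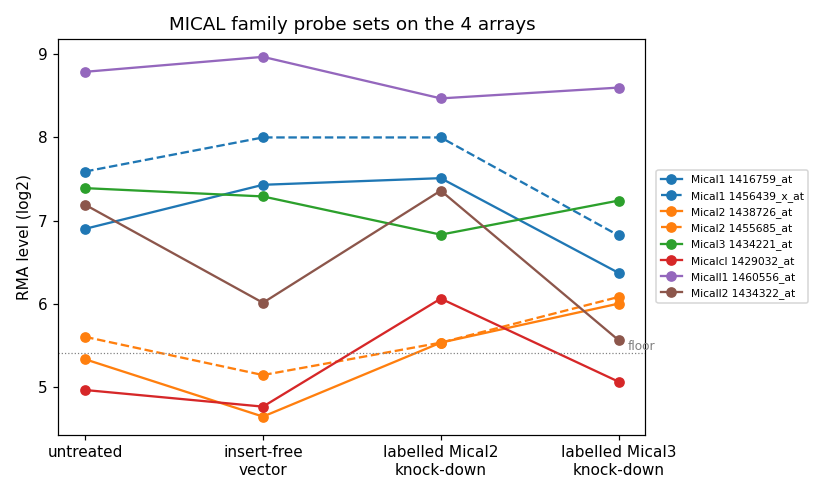
Log2 level (vertical axis) of each MICAL family probe set with exactly 1 gene symbol. The horizontal axis gives the untreated, insert-free vector, Mical2 hairpin and Mical3 hairpin arrays, with 1 point per probe set and array and no replicates. Lines join the points of a probe set, and the dotted line is the floor of 5.41. Both Mical2 probe sets are lowest on the vector array (4.64 and 5.14) and highest on the array labelled Mical3 (6.0 and 6.08).

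The comparison of the Mical2 hairpin with the controls was designed to show which transcripts change when the actin-modifying enzyme is reduced, a reduction that its transcript did not show here. Cd34, a sialomucin of endothelial and blood progenitor cells, stood at 10.02 on the array labelled Mical2 and below the floor on the other arrays (3.76 on the vector, 4.29 on the untreated array). Lipo3, a lipase, was at 8.90, against 3.46 and 4.02. Also higher were Gsta3, a glutathione transferase, at 8.96 (4.80 on the vector and 5.27 on the untreated array), Nnmt, nicotinamide N-methyltransferase, at 9.71 (6.46 and 6.70), and Nqo1, a quinone reductase, at 9.84 (6.98 and 7.01). Lpl, lipoprotein lipase, was lower, at 5.35 against 11.23 and 11.91, as was Sulf1, an extracellular heparan sulfate sulfatase, at 4.71 against 9.95 and 10.19. In all, 118 genes were called higher and 211 lower against both control arrays, 329 of the 12072 genes at or above the floor.

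Other genes higher on the array labelled Mical2 were Ms4a4d (9.41, with 5.88 on the vector and 5.90 on the untreated array), the RNA-binding protein gene Khdrbs3 (6.87, with 3.91 and 3.78), the bile acid receptor gene Nr1h4 (8.77, with 4.52 and 5.87), Prr9 (7.74, with 4.32 and 5.08), the engulfment receptor gene Megf10 (6.96, with 4.46 and 4.21) and Tph2, a tryptophan hydroxylase (6.05, with 3.15 and 3.56). Mycn was at 9.12 (4.16 and 6.34), but its other 2 probe sets differed from the vector array by 0.26 and 0.16. Other genes lower there were Churc1 (4.52, with 11.94 and 10.97), the chemokine gene Cxcl15 (3.92, with 11.34 and 8.79), Bhlhb9 (4.81, with 10.06 and 9.65), Armcx1 (4.04, with 8.43 and 8.17), the small GTPase gene Rab29 (5.34, with 9.82 and 9.31), the mitochondrial carnitine carrier gene Slc25a20 (6.43, with 10.67 and 10.05), the dystrophin gene Dmd (3.74, with 7.14 and 7.28), Nudt12 (3.20, with 7.22 and 6.51) and Kbtbd7 (5.45, with 8.65 and 8.69). Fkbp11 was at 5.47 against 9.77 and 9.74 by a probe set open to cross-hybridisation, while its other probe sets differed from the vector array by -0.52 and 0.23.

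Interferon response genes were lower as a group. Of 39 measured members, 12 were called lower and none higher. Ifit3 stood at 8.69 (11.88 on the vector and 10.07 on the untreated array), Rsad2 at 9.54 (12.44 and 11.02), Dhx58 at 6.05 (9.88 and 7.70) and Igtp at 8.58 (11.58 and 9.91). The others were Ifit1 (10.78, with 13.10 and 12.05), Ifit2 (8.60, with 10.94 and 9.62), Isg20 (9.99, with 12.56 and 11.37), Oasl2 (7.73, with 10.19 and 9.18), Usp18 (10.01, with 12.84 and 11.11), Ifi47 (8.06, with 10.13 and 9.78), Cxcl10 (11.29, with 12.51 and 12.38) and Parp14 (7.56, with 10.05 and 8.91). The median difference was -1.77 from the vector array and -0.62 from the untreated array, each below all 10000 random lists of like size and level. Antigen presentation genes, which share members with that list, had medians of -0.41 and -0.36, with none of 16 called. Tap1 was at 6.54 (8.42 and 6.89), Psmb9 at 7.70 (10.05 and 8.68), Tap2 at 7.16 (8.56 and 7.78) and H2-K1 at 8.88 (10.28 and 9.67).

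Of 31 NRF2 and antioxidant genes, Nqo1 and Gsta3 were called higher and Gstm5, a glutathione transferase, lower (8.84, with 11.18 on the vector and 10.41 on the untreated array). Hmox1, heme oxygenase, was at 11.27 (9.30 and 10.31). The list's medians of 0.39 from the vector and 0.24 from the untreated array lay above all random lists. Among 24 genes that VEGF induces early, 4 were called higher, the growth factor gene Hbegf (9.19, with 7.67 and 8.16), the cyclooxygenase gene Ptgs2 (10.17, with 7.82 and 9.15), Fosl1 (8.97, with 7.54 and 7.38) and Klf2 (8.56, with 7.39 and 6.95), and the list's medians were 0.46 and 0.30. Of 17 immediate early genes driven by ternary complex factors, 2 were called higher, Fos (10.40, with 8.71 and 8.67) and Klf6 (10.89, with 9.39 and 9.88). In the mesenchymal transition list Mmp2 was called higher of 17 genes (8.09, with 6.64 and 7.06), with medians of 0.58 and 0.16. Of the 37 lists, 5 (interferon response, antigen presentation, NRF2, VEGF early and mesenchymal transition) lay outside the central 95% of random lists in 1 direction against both controls.

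SRF and MRTF targets had no called gene among 40. Their median was 0.47 from the vector array, above all random lists, and 0.01 from the untreated array, at the 64.8th percentile. Tagln, a smooth muscle actin-binding protein, was at 11.16 with 6.47 on the vector and 10.27 on the untreated array, Acta2, smooth muscle actin, at 13.80 with 11.61 and 13.67, Ccn2 at 13.10 with 10.54 and 12.78, and Arhgdib at 11.93 with 8.60 and 11.78. The extracellular matrix list had Col6a3 (7.32, with 4.85 and 5.29) and Vcan (10.23, with 7.71 and 8.86) called higher of 42. Its medians were 0.81 from the vector array, above all random lists, and -0.12 from the untreated array, at the 0.615th percentile. Cholesterol synthesis genes had medians of 0.83, above all random lists, and -0.17, at the 10.2nd percentile, over 20 genes and only Tm7sf2 called, as lower (5.30, with 7.72 and 7.93). Of 35 angiogenic growth factors and receptors Flt4, the receptor of VEGF-C, was the 1 called, as lower (7.66, with 8.90 and 9.18), and the medians were 0.27 and 0.04. The 41 actin assembly genes and 23 focal adhesion genes had no called member, with medians from the untreated array of -0.01 and -0.07.

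The count rests on both controls being used. With the vector array as the only control 1286 genes were called, and with the untreated array alone 463. For scale, 200 simulated arrays with no change, given the spread of the 2 controls, were called at 44.9 genes on average and 68 at most. In a simulation that gave every array the spread, 136 of 17993 unchanged genes were called.

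**Figure D2:**
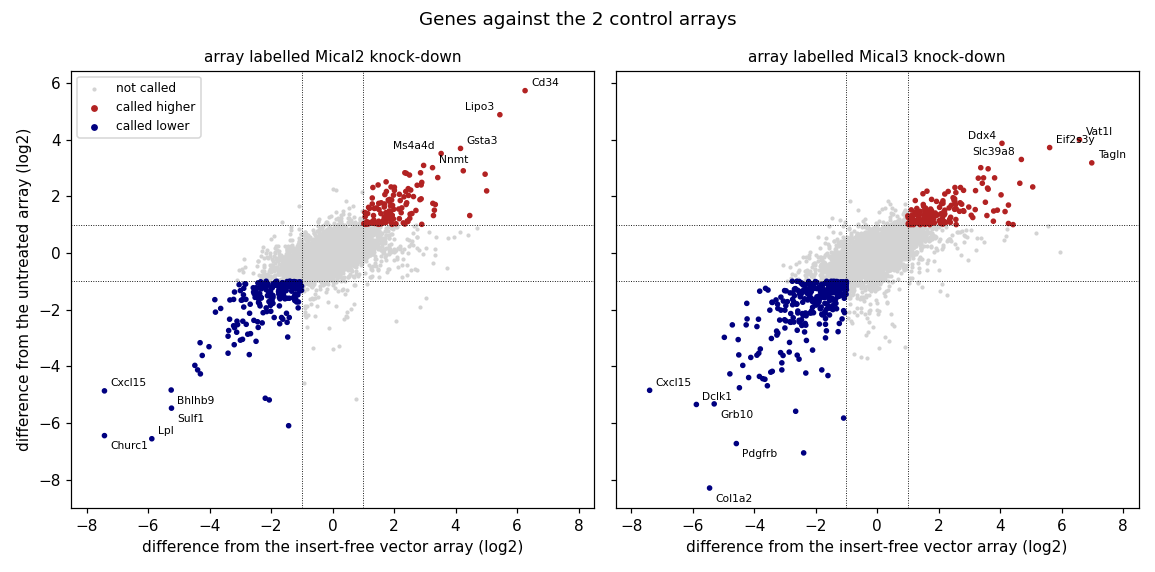
Log2 difference of each gene at or above the floor from the vector array (horizontal axis) and from the untreated array (vertical axis), for the array labelled Mical2 (left) and the array labelled Mical3 (right), 1 point per gene. Red points are called higher and blue points lower against both controls, dotted lines mark 2-fold, and the spread is wider along the horizontal axis, which has the vector array as its control.

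The Mical3 hairpin serves as a related-gene comparison with the same backbone. On the array labelled Mical3, Tagln stood at 13.45 (6.47 on the vector, 10.27 on the untreated array), and the SRF and MRTF targets Actg2 (7.07, with 3.96 and 5.82), Acta1 (7.93, with 6.23 and 6.81), Fhl1 (12.62, with 10.21 and 10.94) and Zyx, a focal adhesion protein (11.10, with 8.86 and 10.02), were called higher as well, 5 of 40 in all. Lower were Col1a2, a chain of type I collagen, at 6.19 against 11.64 and 14.49, Pdgfrb, a receptor of platelet-derived growth factor, at 3.55 against 8.13 and 10.28, and Grb10, an adaptor of insulin receptor signalling, at 4.34 against 9.64 and 9.67. A second Pdgfrb probe set, with a mean level of 6.45, differed by only -0.38 from the vector array and -1.41 from the untreated array. Other Grb10 probe sets, with means below the floor, differed from the vector array by -0.24 and -0.48. In all, 166 genes were called higher and 299 lower against both controls, 465 of 12011.

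The other genes named by rank were Vat1l (11.25, with 4.67 on the vector and 7.25 on the untreated array), the germ cell helicase gene Ddx4 (7.34, with 3.28 and 3.47), the zinc and manganese transporter gene Slc39a8 (9.0, with 4.31 and 5.70) and the proprotein convertase gene Pcsk5 (8.66, with 4.84 and 6.01). Y-linked genes were among the higher ones, Eif2s3y (8.75, with 3.14 and 5.03), Uty (7.18, with 3.81 and 4.17) and Kdm5d (7.15, with 3.54 and 4.18). Those lower included the kinase gene Dclk1 (4.05, with 9.93 and 9.40), Cxcl15 (3.94, with 11.34 and 8.79), Eva1b (5.35, with 9.83 and 10.11), Ptgfrn (4.76, with 9.55 and 9.03) and the glycolipid enzyme gene B4galt6 (4.52, with 8.70 and 8.92).

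Lists tied to the cytoskeleton stood higher against both controls. For SRF and MRTF targets the medians were 0.62 from the vector and 0.17 from the untreated array, the second at the 99.5th percentile of random lists. Of 23 focal adhesion genes 4 were called higher, Itga6 (10.20, with 8.63 and 8.74), Zyx, Cav1 (13.13, with 11.67 and 12.02) and Cd44 (12.14, with 11.06 and 10.98), and Itgb5 was called lower (8.90, with 10.64 and 10.47), with medians of 0.68 and 0.38. Of 21 YAP and TEAD targets Ankrd1 (11.66, with 10.16 and 10.47), Crim1 (9.94, with 8.37 and 8.85) and the tissue factor gene F3 (10.51, with 9.22 and 8.94) were called higher, with medians of 0.38 and 0.38. Actin assembly genes had none of 41 called, with medians of 0.31 and 0.16 and with Coro1c at 10.35 (8.77 and 9.66), Limk1 at 8.99 (7.08 and 8.06), Ezr at 13.44 (11.67 and 12.51) and Diaph3 at 9.10 (7.88 and 8.54).

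Among 24 genes that VEGF induces early, Dusp5 (9.76, with 7.65 and 8.59), Dusp6 (11.60, with 9.64 and 10.26), F3 and Hbegf (9.34, with 7.67 and 8.16) were called higher, and Egr2 (4.13, with 5.31 and 5.62) and Ptgs2 (5.72, with 7.82 and 9.15) lower, with medians of 0.22 and 0.27. This list and the 4 described above, of SRF and MRTF targets, focal adhesion, YAP and TEAD targets and actin assembly, lay outside the central 95% of random lists in 1 direction against both controls. Of the immediate early genes driven by ternary complex factors, Fos (10.01, with 8.71 and 8.67), Ier3 (13.10, with 10.92 and 11.76), Klf6 (11.05, with 9.39 and 9.88) and Dusp1 (12.21, with 8.92 and 9.57) were called higher and Egr2 lower, of 17.

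Angiogenic growth factors and receptors had 6 of 35 genes called lower and none higher on the array labelled Mical3. They were Vegfc (6.64, with 8.32 and 9.16), Vegfd (6.03, with 8.16 and 8.07), Flt4 (7.55, with 8.90 and 9.18), Fgfr1 (5.03, with 7.18 and 6.62), Pdgfrb and the chemokine gene Cxcl12 (9.32, with 12.46 and 12.84), while the list's medians were 0.01 and -0.04, inside the range of random lists. Mesenchymal transition genes had Snai2 (9.27, with 10.99 and 10.57), Twist2 (6.09, with 10.00 and 9.70) and Prrx1 (5.73, with 7.53 and 9.86) called lower of 17. The list's medians were 0.08 from the vector and -0.59 from the untreated array. In the extracellular matrix list Nid1 (7.06, with 4.49 and 6.06), Loxl1 (6.69, with 4.88 and 5.48) and Igfbp7 (13.00, with 9.09 and 11.49) were called higher and Col1a2 and Tnc (7.64, with 8.92 and 8.76) lower, and the medians were 0.23 from the vector and -0.36 from the untreated array. Interferon genes had medians of -0.93 and 0.07, with Psmb8 (7.14, with 5.41 and 5.96) the 1 called, as higher. With the vector array as the only control 1402 genes were called, and with the untreated array alone 670.

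The insert-free vector against the untreated array was designed to measure what transduction and selection do, together with the difference between any 2 arrays. This reading rests on the vector label, and a swap with the Mical2 label, taken up below, stays open. Interferon response genes were higher on the vector array in 22 of 39 cases and lower in none, with a median of 1.02. Oas3 stood at 6.87 against 4.84 on the untreated array, Dhx58 at 9.88 against 7.70, Mx2 at 8.88 against 6.95 and Irf7, a transcription factor of the response, at 9.56 against 7.78. Extracellular matrix genes were lower in 22 of 42 cases and higher in none, with a median of -1.06. Col8a1 stood at 4.47 against 9.09, Nid2 at 4.18 against 7.58, Postn at 5.56 against 8.92 and Col3a1 at 10.30 against 13.29. The rule called 386 genes higher and 305 lower, 691 in all. Against the untreated array alone the hairpin arrays had 463 and 670. The balance of directions depended on the settings, with 76 higher and 119 lower at 3-fold and 335 and 339 after loess.

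The genes furthest apart in this comparison were Capg, an actin-capping protein (11.06 on the vector array, 8.32 untreated), Ifi27l2a (12.75 and 10.03), the coactivator gene Ppargc1a (6.84 and 4.19), Cxcl15 (11.34 and 8.79) and the stress transcription factor gene Atf3 (10.31 and 7.82) among the higher, and the cadherin gene Cdh11 (4.68 and 10.60), the proteoglycan gene Fmod (5.89 and 10.63), the chemokine gene Cxcl5 (6.28 and 10.95), Col8a1 and the guidance factor gene Slit2 (5.11 and 9.59) among the lower. Of 29 genes of the integrated stress response 7 were called higher, among them Ddit3 (13.08 and 11.06), Trib3 (12.12 and 10.06), Ppp1r15a (10.49 and 8.68) and Chac1 (11.77 and 10.19), the others being Atf3, Sesn2 (9.49 and 8.39) and Nupr1 (12.68 and 11.28). Of 20 p53 targets Cdkn1a (11.25 and 9.88), Trp53inp1 (11.31 and 9.06), Sesn2, Gadd45a (11.17 and 9.48) and Eda2r (7.89 and 5.78) were called higher and Fas (7.42 and 8.66) lower, and Cdkn1a was also at 11.19 and 11.32 on the arrays labelled Mical2 and Mical3. Cholesterol synthesis genes had 7 of 20 called lower, among them Idi1 (9.79 and 11.45), Hmgcs1 (11.02 and 12.48), Cyp51 (9.01 and 10.36) and Sqle (9.63 and 10.88), with a median of -0.70. The remaining called members were Nsdhl (8.69 and 9.86), Msmo1 (9.38 and 10.49) and Mvk (7.48 and 8.51).

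Of the 40 SRF and MRTF targets 7 were called lower on the vector array, namely Tagln (6.47 and 10.27), Arhgdib (8.60 and 11.78), Ccn2 (10.54 and 12.78), Acta2 (11.61 and 13.67), Actg2 (3.96 and 5.82), Thbs1 (9.16 and 10.73) and Zyx (8.86 and 10.02), and none higher, with a median of -0.48 that lay below all random lists. The medians of focal adhesion genes (-0.20) and actin assembly genes (-0.18) also lay below the 2.5th percentile. G2/M genes had Plk1 (8.73 and 9.86) and Kif23 (8.98 and 10.04) called lower of 27, with a median of -0.45. In all, 19 of the 37 lists lay outside the central 95% of random lists, 4 of them above and 15 below.

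The spiked poly(A) controls, bacterial transcripts added before labelling, also differed on this array. Their 5' probe sets had a median difference of -0.61 from the untreated array, those in the middle of the transcripts -0.46 and those at the 3' end -0.25, whereas the hybridisation controls differed by 0.06. On the array labelled Mical2 the 5' probe sets differed from the untreated array by 0.43. The 3 probe sets of 18S ribosomal RNA were lower than on the untreated array on all 3 transduced arrays, with medians of -0.22 on the vector array, -0.83 on the array labelled Mical2 and -0.65 on that labelled Mical3. The difference between the 3' and 5' probe sets of actin was 0.18 on the vector array and 0.03 to 0.06 on the others. For GAPDH it was -0.13 on the vector array, -0.15 on the untreated array, and -0.22 and -0.19 on the arrays labelled Mical2 and Mical3.

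**Figure D3:**
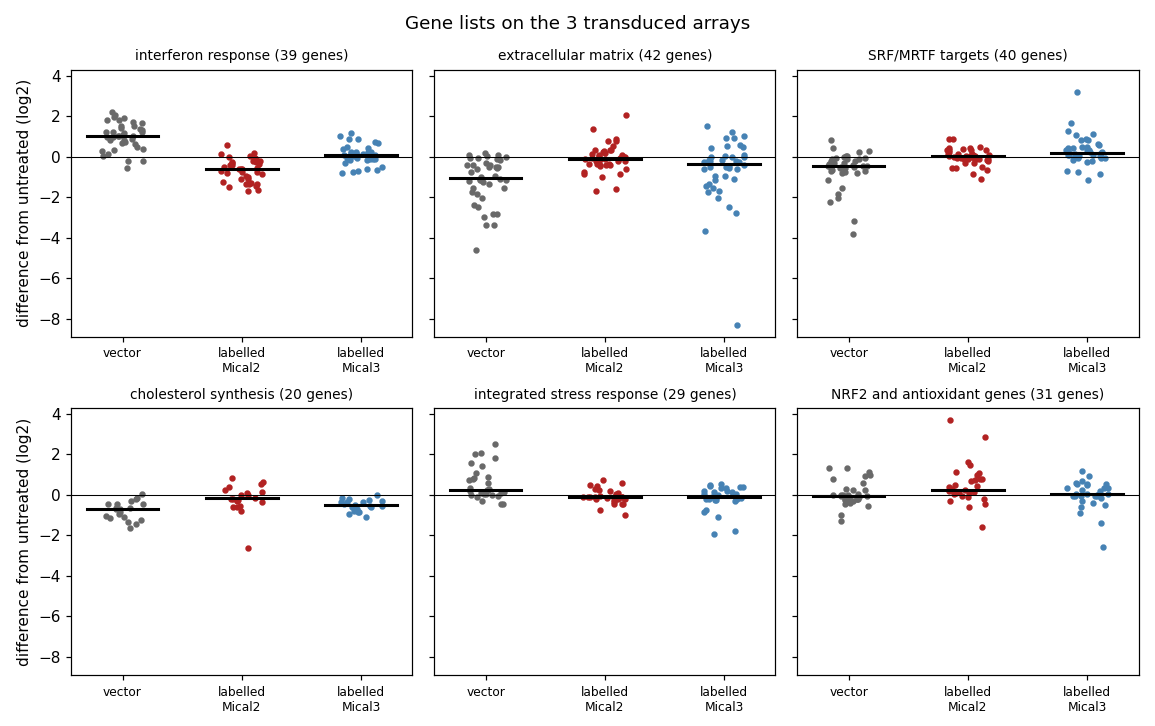
Log2 difference from the untreated array (vertical axis) of the measured members of 6 gene lists on the vector array and the arrays labelled Mical2 and Mical3 (horizontal axis), 1 point per gene and array, with a bar at the median. Interferon genes lie above 0 on the vector array (median 1.02) and below it on the array labelled Mical2 (-0.62), and extracellular matrix genes have their lowest median on the vector array (-1.06).

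The 2 hairpin arrays were also set against each other, which uses no control array. Col1a2 stood at 14.06 on the array labelled Mical2 and 6.19 on that labelled Mical3, Pdgfrb at 10.71 and 3.55, Cd34 at 10.02 and 3.93, the lipid phosphatase gene Plpp3 at 10.30 and 4.44, and Plac8 at 10.00 and 4.23. In the other direction Vat1l was at 5.15 and 11.25, Churc1 at 4.52 and 10.59, Sulf1 at 4.71 and 10.60, Lpl at 5.35 and 11.13, and the chromatin organiser gene Satb1 at 3.68 and 9.37. The rule called 454 genes higher and 444 lower on the array labelled Mical2, a balance that changed with the settings (966 and 1321 at 1.5-fold, 218 and 157 at 3-fold, 471 and 388 after loess). Interferon genes were lower there in 13 of 39 cases (median -0.68) and extracellular matrix genes higher in 12 and lower in 3 of 42 (median 0.15). Hypoxia and glycolysis genes were higher in 5 and lower in 2 of 30 (median 0.32), and NRF2 and antioxidant genes higher in 6 and lower in 2 of 31 (median 0.23).

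Each array was compared with the other 3 in the same way. Against all 3 others, the untreated array differed 2-fold at 30 genes, the vector array at 341, the array labelled Mical2 at 201 and the array labelled Mical3 at 309. The vector array had more of them higher than lower at 2-fold (213 and 128) but not at 3-fold (40 and 48). Some genes were bright on 3 arrays and below the floor on 1. Churc1, Lpl, Rab29 and Sulf1 were below the floor on the array labelled Mical2 and at 8 or more on the others, and 11 genes were so on the array labelled Mical3, among them Dclk1, Grb10, Pdgfrb (by its brightest probe set) and Ptgfrn. Cd34 and Lipo3 showed the opposite, being bright only on the array labelled Mical2. Some genes called for the array labelled Mical2 had a second probe set that also had a mean at or above the floor. That one differed from the vector array in the same direction in 107 of 113 cases, and for the array labelled Mical3 in 159 of 169. Dimmer probe sets were not counted. Of other probe sets with a mean at or above the floor, 53 of 169 and 82 of 271 differed from at least 1 control by less than 0.50 in the direction of the call, a tally chosen after the values were seen. Such genes named here, besides Mycn, Fkbp11 and Pdgfrb, were Selp on the array labelled Mical2, Fmod, Gstm1, Gusb, Igfbp7 and Spry2 on that labelled Mical3, and Flt4 on both.

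**Figure D4:**
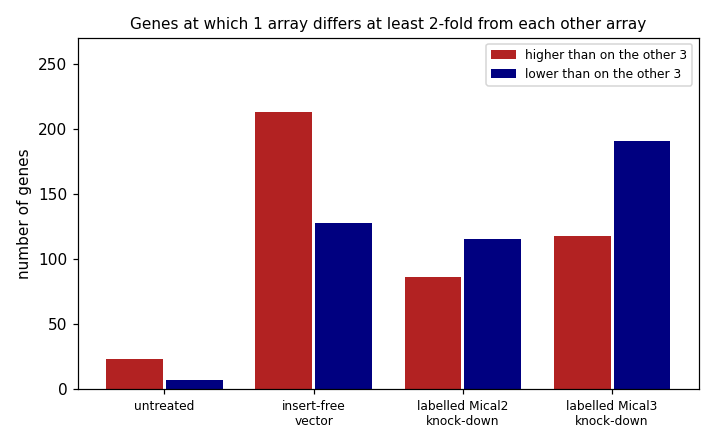
Number of genes (vertical axis) that were at least 2-fold higher (red) or lower (blue) on 1 array than on each of the other 3, for the 4 arrays (horizontal axis), with no replicates. The untreated array has 23 higher and 7 lower, and the vector array 213 higher and 128 lower.

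Genes called in the same direction on both hairpin arrays numbered 10 higher and 41 lower. Serpinb9b, a serine protease inhibitor, was at 9.91 and 10.56 on the arrays labelled Mical2 and Mical3 (8.03 on the vector, 8.25 untreated), the natriuretic peptide gene Nppb at 7.63 and 8.29 (5.48 and 6.08) and Mmrn1, a multimerin of platelets and lymphatic endothelium, at 6.67 and 6.56 (4.47 and 4.82). Mycn read 9.12 and 8.80 by its brightest probe set, with the limit given above. Cxcl15 was at 3.92 and 3.94 (11.34 and 8.79), Bhlhb9 at 4.81 and 6.26 (10.06 and 9.65), the secreted factor gene Ndnf at 4.31 and 4.62 (7.07 and 7.18), and the imprinted zinc finger gene Plagl1 at 4.29 and 3.94 (7.21 and 6.70). Plagl1 was read by a probe set open to cross-hybridisation. Its other probe sets, with means below the floor, differed from the vector array by 0.47 and 0.18 on the array labelled Mical2. Independent lists of these sizes would share 1.61 higher and 5.19 lower genes, and simulated unchanged arrays against the same controls shared 0.115 and 0.125 on average. Neither value removes the share of the overlap that comes from using the same control arrays. The value for independent lists also takes every gene as equally likely to be called. Across genes, which are not independent replicates, the differences of the 2 hairpin arrays correlated at 0.573 with the vector array as the control (0.333 simulated). With the untreated array the correlation was 0.213 (0.334 simulated). The covariance less the simulated one was 0.221 and -0.0103 in the same order. The simulated arrays were set midway between the 2 controls, which fixes their correlation near 0.333 whatever the data. The vector array stood further apart from the others than the untreated array did, so the simulated values do not remove the part due to the shared control. With a separate control array for each, the correlation was 0.0961 or 0.103.

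Markers of endothelial cells and of other cell types were read on the same arrays. Of 30 pan-endothelial genes 14 reached the floor on any array, and Pecam1, Cdh5, Tek and Vwf did not. Cd34 was called higher on the array labelled Mical2, and on the array labelled Mical3 Mcam was called higher (7.90, with 6.04 on the vector and 6.84 on the untreated array) and Fli1 lower (3.59, with 5.78 and 5.71). Of 12 lymphatic endothelial genes, Mmrn1 was called higher and Flt4 lower on both hairpin arrays, while Pdpn was bright on all 4 (11.67 to 12.50). Fibroblast markers were lower on the vector array in 6 of 12 cases, among them Pdgfra (6.16, with 10.40 untreated) and Postn, with a median of -1.21, and Col1a2 and Dpt (5.01, with 7.05 on the vector and 6.66 on the untreated array) were called lower on the array labelled Mical3. The list's median there was -1.09 from the untreated and 0.09 from the vector array. Leukocyte markers had a median of 0.11 on the vector array over 16 genes, with Cd68 higher (8.0 and 5.93) and Cd14 lower (5.75 and 7.04), and Cd14 was called higher on the array labelled Mical2 (8.26). Of 13 pericyte and smooth muscle genes, Mylk was called higher on the array labelled Mical2 (9.41, with 7.68 and 7.99) and Pdgfrb lower on that labelled Mical3. Of 15 epithelial genes, Krt14 was called higher on the array labelled Mical2 (7.28, with 5.11 and 6.07) and Krt18 on that labelled Mical3 (7.41, with 4.84 and 5.85).

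TGF-beta and BMP targets had Id2 (11.10, with 9.16 on the vector and 9.77 on the untreated array) and Bambi (6.73, with 5.62 and 5.63) called higher on the array labelled Mical2 and Ltbp1 (6.64, with 8.94 and 9.73) lower on the array labelled Mical3, of 23. Matrix proteases had Mmp2 higher on the array labelled Mical2, and Mmp3 (4.60, with 7.44 and 7.03) and Mmp11 (6.87, with 8.36 and 7.91) lower on that labelled Mical3, of 25. NF-kB inflammatory genes had Selp (8.30, with 5.98 and 6.32) and Ptgs2 higher and Cxcl5 (4.85, with 6.28 and 10.95) and Nfkbie (7.89, with 9.47 and 9.47) lower on the array labelled Mical2, and Cxcl1 (8.42, with 10.02 and 12.75), Cxcl5 (3.89), Saa3 (7.94, with 10.54 and 11.55) and Ptgs2 lower on that labelled Mical3, of 29. Semaphorin and plexin genes had Dpysl3 higher on the array labelled Mical2 (10.60, with 8.92 and 9.33) and lower on that labelled Mical3 (7.14), where Sema6d (8.83, with 5.31 and 7.04) and Sema4a (5.99, with 4.43 and 4.98) were higher, of 29. Integrated stress genes had Aldh1l2 (9.06, with 10.57 and 11.02), Fgf21 (5.53, with 8.14 and 7.33) and Ddit4 (8.52, with 9.58 and 9.61) lower on the array labelled Mical3 and none called on that labelled Mical2, of 29. The list's medians were -0.50 and -0.38 from the vector array and -0.12 and -0.09 from the untreated array on the arrays labelled Mical2 and Mical3. Hypoxia and glycolysis genes had Bnip3 (5.76, with 10.13 and 9.73) and Ddit4 lower on the array labelled Mical3, of 30, and Bnip3 was also the 1 of 26 apoptosis regulators called there.

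On the array labelled Mical2, Foxf2 (8.16, with 7.08 on the vector and 7.15 on the untreated array) was called higher of 21 YAP and TEAD targets, and Hspb1 (11.67, with 13.16 and 12.85) was called lower of 16 heat shock genes. NRF2 and antioxidant genes had Gsta4 (11.98, with 10.81 and 10.80) higher and Gstm1 (6.48, with 10.39 and 9.08) and Cbr3 (7.90, with 9.33 and 9.30) lower on the array labelled Mical3. Small RNA machinery genes, which process hairpins, had Ago1 lower on the array labelled Mical2 (7.37, with 9.38 and 9.43) and Tnrc6b lower on that labelled Mical3 (7.88, with 9.03 and 8.92), of 16. Of 11 housekeeping genes Gusb was called lower on the array labelled Mical3 (8.25, with 9.54 and 9.76). No member was called on either hairpin array among 25 S phase genes, 27 G2/M genes, 20 p53 targets, 22 genes of the unfolded protein response, 27 cytosolic ribosomal protein genes and 32 genes of oxidative phosphorylation. Their medians from the untreated array were 0.02 and 0.06 for S phase, -0.13 and -0.06 for G2/M, 0.26 and 0.14 for p53 targets, -0.20 and -0.17 for the unfolded protein response, 0.00 and -0.01 for ribosomal proteins, and 0.02 and -0.05 for oxidative phosphorylation, on the arrays labelled Mical2 and Mical3. From the vector array they were -0.07 and -0.02, 0.32 and 0.38, 0.08 and -0.02, 0.03 and 0.16, -0.01 and 0.00, and -0.07 and -0.11 in the same order.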

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

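The tests in this part were chosen after the result was seen, except the loess setting for the interferon genes.

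Genes called on both hairpin arrays in opposite directions numbered 20, against 5.78 for independent lists, a difference between the arrays that was not tested. That expectation takes every gene as equally likely to be called, and no simulated value was made for opposite directions. Plpp3 was higher on the array labelled Mical2 than on the array labelled Mical3 by 5.86, Ptgs2 by 4.45 and Dpysl3 by 3.46. Among probe sets with no gene symbol, which the comparisons left out, 26 passed the size rule for the array labelled Mical2 and 35 for the array labelled Mical3. Among control probe sets, those at the 5' end of the spiked phe and dap transcripts were brighter on the array labelled Mical2 than on the vector array by a median of 1.59 and than on the untreated array by 0.52.

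The pattern with most bearing on the labels is that neither target was lower on the array of its own hairpin by more than the spread between probe sets. A swap of the 2 hairpin labels would need Mical2 to be lower on the array labelled Mical3, where it was higher than on either control array by 0.48 at the least, although Mical3 itself was lower on the array labelled Mical2 (6.83, against 7.29 and 7.39). Whether the Mical2 probe sets read only background could not be decided. The smaller of their 2 ranges over the arrays was 0.94, against a limit of 0.72, and both had their lowest and highest levels on the same arrays. That limit, however, came from the difference of 2 arrays at genes at or above the floor. Among genes below the floor on all 4 arrays, Slc38a4 ran from 3.63 to 4.64, while Nap1l5 stayed between 3.98 and 4.10. A swap of the vector and Mical2 labels stays open as a candidate explanation, because both Mical2 probe sets were lowest on the vector array. The difference nearest to 0 from another array was -0.39. The SRF and MRTF targets, a list that includes Mical2 itself, were lower there too (median -0.48 from untreated). That drop was not specific to this list, since 15 of the 37 lists lay below the 2.5th percentile of random lists there. It therefore does not single out a loss of Mical2. The Mical2 levels also lie near the floor, and with 1 pooled array per group a wrong label and a different culture cannot be told apart. Hairpins that act on the protein more than on the transcript, or a knock-down lost in culture, were not tested.

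The vector array stood apart from the other 3 at 341 genes, with interferon genes higher. A trend with level between arrays is argued against by the median of the interferon list after loess, which was 1.03, and leukocytes in that culture by the leukocyte marker median of 0.11, although Cd68 was higher by 2.07. Transduction and selection as such would also raise these genes on the hairpin arrays, but the higher of their 2 medians from the untreated array was 0.07. What stays open is a state of that culture or pool, which may include a response to that vector preparation, and the swap of the vector and Mical2 labels considered above. Under such a swap the interferon genes would be higher on an array with a hairpin. The lower signal of the poly(A) controls on the vector array is no level of the cells, since these transcripts were added before labelling. It was strongest at their 5' probe sets (-0.61, against -0.25 at the 3' end), while the hybridisation controls differed by 0.06. A technical difference of that array, in the spiking or the labelling, therefore stays open as well. Its share in the gene differences from the vector array was not tested.

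The 3 transduced arrays each departed from the untreated array, in part at different genes, and a few genes were nearly on or off. The 2 hairpin arrays shared 10 genes called higher and 41 called lower. Genes below the floor on 1 array and at 8 or more on the other 3 numbered 1 for the vector array, 4 for the array labelled Mical2 and 11 for that labelled Mical3. Another 2 were bright only on the array labelled Mical2. Failing probe sets are argued against only for called genes with a second probe set at or above the floor. In the lowest of 5 comparisons that probe set moved the same way in 93.8% of cases, though it reached a difference of 1 in 42.5%. Called genes whose other probe sets are all dimmer are not covered. Gains or losses of chromosome segments would carry the neighbours of called genes along, but the median difference of the nearest neighbours, signed by the call, was 0.10 on the array labelled Mical2 and 0.14 on that labelled Mical3, under the 0.29 that is 1/2 of a 1-copy gain though above all 1000 random orders (0.06 at most), so that segments could account for some of the genes but not for most. Whether different mixes of cell lineages after selection account for the pattern could not be decided. On the array labelled Mical3, 3 of 6 measured Y-linked genes were higher than on the untreated array by 2.97 or more. Sry (6.17 and 6.09) was not, nor were Zfy2 (3.97 and 3.92) and Usp9y (4.34 and 4.52), which lay below the floor on all 4 arrays. All of these genes lie on 1 chromosome, so their shift could also come from a gain or loss there. Dim probe sets of the 3 higher genes moved less from the vector array. They differed by -0.05 and -0.13 for Kdm5d, 0.38 for Eif2s3y, and 0.25, 0.42 and 1.61 for Uty. On the array labelled Mical2 and on the vector array a difference of at least 1 was seen for Eif2s3y only (6.04 and 3.14, with 5.03 untreated). Lineage, a change of the Y chromosome and the hairpins, the biological explanation that the design gives, therefore cannot be told apart.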

How the results depend on the processing

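All settings in this part were planned. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. Without a floor, with the most variable probe set, without probe sets open to cross-hybridisation, after a repeated quantile normalization or loess, and with 16 added on the linear scale, every count of called genes stayed within 1.5 times its value. With the vector array as the only control 1286 genes were called for the array labelled Mical2, 1402 for the array labelled Mical3 and 598 for both in 1 direction (34.9% of them higher, against 19.6%). With the untreated array alone 97 were shared, and with the mean of the controls the counts were 632, 862 and 188. At 1.5-fold the counts were 979 and 1323 for the arrays labelled Mical2 and Mical3, 2084 for the vector against untreated, 2287 between the hairpin arrays and 248 shared, and the untreated, vector, Mical2 and Mical3 arrays stood apart at 115, 1117, 557 and 803 genes. At 3-fold they were 112, 163, 195, 375 and 14, and 12, 88, 83 and 117. A floor at the 75th percentile left 206 genes for the array labelled Mical2, 446 for the vector, 579 between the hairpin arrays, 16 for the untreated array apart from the others and 27 shared. The mean of all probe sets gave 218 for the array labelled Mical2, 29 shared and 203 by which the array labelled Mical3 stood apart. The changes with fold and floor follow from the thresholds, and the cause of the others was not tested.

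List medians of the hairpin arrays that lay outside the central 95% of random lists and changed sign did so with the control. From the untreated array alone the medians on the array labelled Mical2 were -0.12 for extracellular matrix, -0.13 for G2/M, -0.075 for heat shock, -0.17 for cholesterol synthesis and -0.23 for fibroblast markers. On the array labelled Mical3 they were -0.36 for extracellular matrix, -0.06 for G2/M, 0.07 for interferon, -0.51 for cholesterol synthesis and -0.04 for epithelial markers. From the mean of the controls, extracellular matrix was at -0.06 and cholesterol synthesis at -0.0225 on the array labelled Mical3. Fkbp11 turned to 0.23 on the array labelled Mical2 without probe sets open to cross-hybridisation. Of the values of named genes under the alternatives, 316 of 440 stayed within the spread between probe sets, 123 moved further and 1 changed sign, and of those of list medians 863 of 1036 stayed within the spread of random lists, 161 moved further and 12 changed sign as above. The 161 include medians inside the central 95% that also changed sign, such as those on the array labelled Mical3 from the untreated array alone of mesenchymal transition (-0.59) and fibroblast markers (-1.09). With random lists not matched on level, 13 of 148 list medians changed side of the central 95%. Signal over background limits the Mical2 probe sets and the endothelial markers below the floor.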

Other observations

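All tests in this part were chosen after the result was seen, on lists drawn up then.

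Some imprinted genes were among those that went nearly on or off, and are given as values because the list was made after they had been seen. Of 31 measured, 5 were called on a hairpin array and 26 were not. Grb10 was at 4.34 on the array labelled Mical3 and between 9.64 and 9.98 on the others, by its brightest probe set and with the limit given above for its dimmer ones. Plagl1 was at 4.29 and 3.94 on the arrays labelled Mical2 and Mical3 (7.21 on the vector and 6.70 on the untreated array), with the limit given above for its probe sets. Sgce was at 6.46 and 5.30 (7.66 and 8.09), and Sfmbt2 at 5.97 and 4.48 (7.48 and 7.13). Peg3 went the other way on the array labelled Mical3, with 11.81 there, 8.03 on the array labelled Mical2, 7.65 on the vector array and 10.35 on the untreated array.

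Of 10 targets and feedback inhibitors of the ERK kinase pathway, on a list drawn up after some had been seen, 5 were called higher on the array labelled Mical3. Etv4 stood at 7.80 (5.66 on the vector, 6.05 untreated), Etv5 at 7.75 (5.05 and 5.98), Spry2 at 9.47 (7.35 and 8.24, although its second probe set above the floor differed by only 0.16 and -0.07), Dusp4 at 11.14 (9.52 and 8.96) and Dusp6 at 11.60 (9.64 and 10.26), while on the array labelled Mical2 none of the 5 was called. Higher output of the ERK pathway as a whole is a hypothesis. The other 5 members of a 10-gene list of its output were Phlda1, Spry4, Ccnd1, Epha2 and Epha4. On the array labelled Mical3 they had a median of 0.73 from the vector array but only 0.03 from the untreated array, so that the test leaves it open. On the array labelled Mical2 all 10 genes had a median of 0.635 from the vector array, above all random lists, with 9 of them higher. From the untreated array it was 0.18, at the 96.0th percentile, with 6 higher.

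The metallothionein genes Mt1 and Mt2 were lower on the array labelled Mical3, at 10.67 and 9.50, with 13.48 and 12.35 on the vector array and 13.12 and 12.66 on the untreated array, and the zinc transporter gene Slc39a8 was higher (9.0, with 4.31 and 5.70). Another Mt1 probe set differed by -1.86 from the vector and -0.50 from the untreated array, and a dim one of Slc39a8 by 0.10 from the vector array. Whether metal-responsive genes as a group were lower on the array labelled Mical3 stays open, since 7 of 11 such genes were higher than on the vector array and 6 than on the untreated array, and their median, at the 86.0th and 87.9th percentiles, lay inside the range of matched random lists. On the array labelled Mical2 none was called, but 10 were higher than on the vector array (median 0.29, 98.6th percentile) and 10 than on the untreated array (median 0.49, above all random lists).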
